A study of Mus musculus with 14 samples.

How the data were processed

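RNA of fluorescence-sorted cells of 14 samples in 5 groups was measured on Affymetrix mouse expression arrays. Per the labels' protocols, RNA was extracted with a column kit and DNase, amplified in a pair of rounds and labelled with biotin. The deposited values are intensity values that, per the submitters' processing notes, were made by RMA, with no version of the software given. The plan assumed log2 values, but the table held linear intensities rounded to whole numbers, so their log2 was taken without a pseudocount before any test. The sorted values were equal in all 14 arrays at 45.1% of ranks, and within 1 unit at 66.1%. The number of arrays limits the precision, and no depth applies to arrays.

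Of 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Of those with 1 symbol, 34741 were named through the gene identifier of the platform table and 1 through an accession, and 203 kept the platform's symbol. The symbol of 1 was updated. Probe sets with several symbols or none were left out of the gene tests. Each gene was represented by its probe set with the highest mean over all 14 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. List members under older symbols were matched through the synonyms of the gene table, and some list members were not analysed here.

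The genes were tested with limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes, in 1 fit of the 14 arrays with a mean per group and no covariate (9 residual and 2.627 prior degrees of freedom). The tests were two-sided, and p was adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. There were 6 comparisons. Differences are the first group named minus the second, on the log2 scale. Genes apart from the other groups passed with the same sign in all 4 comparisons of SEZ_GFPprom. Because these comparisons share SEZ_GFPprom, their count was set against 100 simulations of unchanged groups (seed 11), against the overlap of independent lists and against fits that split the SEZ_GFPprom arrays between comparisons.

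The 30 gene lists were tested with limma's camera at a preset correlation of 0.01, in 180 tests adjusted over the lists within each comparison, and also with an estimated correlation and with fry. The lists were markers of 11 cell types, namely astrocytes, neuroblasts, mature neurons, ependymal cells, oligodendrocytes and their progenitors, microglia, endothelial, mural and choroid plexus cells and erythrocytes, and genes of stem cells, transcription factor groups, cilia, the cell cycle, signalling pathways, metabolism, matrix, interferon, stress and sex. Named genes were the 8 highest and 8 lowest differences per comparison among genes past the threshold whose groups did not overlap, the sorting genes Gfap, Prom1 and Cd24a, up to 4 members of each list with the smallest adjusted p, and the 10 genes in each direction with the largest smallest difference among those apart from all groups. Clone and model names were counted and not named. The list examples printed are a part of those the rule gave, chosen after their values were seen.

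These lists, rules, comparisons and most alternatives were chosen before the data were examined. The alternatives chosen then were quantile normalization, equal medians, cyclic loess, leaving out the dimmest 25% or 50% of genes, the mean of a gene's probe sets, fits of only the groups compared, a block per replicate number, array weights, a trend and robust prior, the log2 3' to 5' signal ratio of the control transcripts as a covariate, and leaving out each array in turn. Chosen after seeing the data were setting values under 10 to 10, and leaving out probe sets whose names mark a sequence shared between transcripts. Bootstrap intervals (95%) came from 10000 draws of a list's genes.

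The fit was tested on simulated data of 18193 genes with 200 changed. For SEZ_GFPprom against DIEC_GFP it recovered 34.3% of genes changed by 1 log2 unit, 89.6% of those changed by 2 and 98.5% of those changed by 3. For SEZ_Prom against SEZ_CD24, with 2 arrays each, it recovered 5.97%, 65.7% and 78.8%. Unchanged genes made up 5.73% and 3.85% of the calls in these comparisons, and at most 6.67%, in SEZ_GFPprom against SEZ_GFP. Among the named genes past the threshold 138 had several probe sets, all past it in the same direction for 41, and 1 had a probe set past it in the opposite direction.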

Results

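RNA from cells sorted out of the brains of 8-week-old hGFAP-eGFP mice, in which the human GFAP promoter drives green fluorescent protein (GFP) in astrocytes and astrocyte-like stem cells, was measured on 14 arrays in 5 groups. The subependymal zone (SEZ), the neurogenic layer along the lateral ventricle, gave 4 of the groups. These were cells positive for both GFP and the surface protein prominin (SEZ_GFPprom, n = 4), for GFP (SEZ_GFP, n = 2), for prominin (SEZ_Prom, n = 2) and for CD24 (SEZ_CD24, n = 2). The fifth group was GFP-positive cells of the diencephalon (DIEC_GFP, n = 4). The labels call the 3 SEZ sorts for GFP or prominin neural stem cells, the CD24 sort ependymal cells and the diencephalic sort astrocytes. The labels name the arrays of a group biological replicates and say no more about separate animals, so p-values measure the spread between these arrays. The number of arrays limits the precision of every value.

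Arrays of the same group correlated at r = 0.942 to 0.979 across genes and arrays of different groups at r = 0.845 to 0.952. No pair of arrays held more than 13.1% identical values across probe sets. The first principal component carried 29.7% of the variance and the second 21.2%. On each array 25.4% to 25.7% of probe sets stood at an intensity of 10 or less, where values were rounded to few steps. For a gene whose mean in a group compared lay under 10, the size of a difference depends on that background, so for such genes it is given with values under 10 set to 10, a setting chosen after seeing the data, and p-values come from the unaltered values unless stated.

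**Figure D1:**
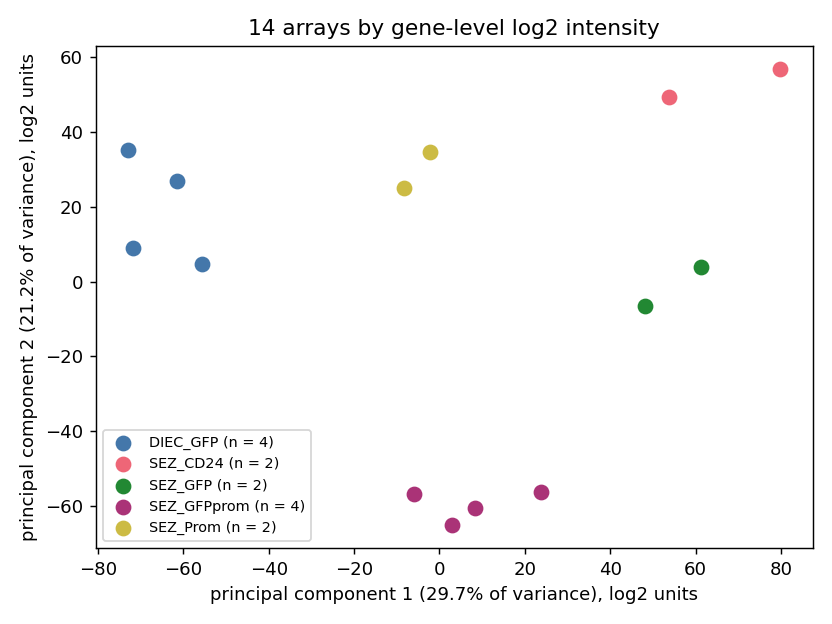
Each point is 1 of the 14 arrays placed by its scores on the first 2 principal components of gene-level log2 intensity (x axis 29.7% and y axis 21.2% of the variance, in log2 units), coloured by sort. The 4 SEZ_GFPprom arrays lie together at the lowest scores of the second component, and the DIEC_GFP arrays lie at the lowest scores of the first.

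The transcripts of the sorting proteins were read first. Gfap stood at log2 8.65 ± 1.11 (SD, n = 4) in SEZ_GFPprom, 8.55 ± 0.48 (n = 4) in DIEC_GFP, 7.68 ± 0.12 (n = 2) in SEZ_GFP, 7.64 ± 0.68 (n = 2) in SEZ_Prom and 5.13 ± 0.06 (n = 2) in SEZ_CD24. Of the 6 comparisons, only SEZ_GFPprom against SEZ_CD24 passed the test for Gfap (11.5-fold, adjusted p = 0.00235). Without probe sets of shared sequence, a setting chosen after seeing the data, that difference was 0.83 (log2, adjusted p = 0.128). Gfap in SEZ_Prom against SEZ_CD24 lay at the threshold (2.51, adjusted p = 0.0501) and passed under several other settings, as without SEZ_GFPprom replicate 3 (adjusted p = 0.0134). Prom1 passed in none of the 6 comparisons, but between SEZ_GFPprom and SEZ_CD24 it passed with cyclic loess (1.51, adjusted p = 0.0477) and without the dimmer 25% (0.0425) or 50% (0.0311) of genes. Its mean was 8.97 ± 0.29 in SEZ_GFPprom, 8.02 ± 0.59 in SEZ_Prom, 8.18 ± 0.36 in SEZ_GFP, 8.03 ± 0.16 in DIEC_GFP and 7.49 ± 1.53 in SEZ_CD24. Without SEZ_CD24 replicate 2 its difference between SEZ_GFPprom and SEZ_CD24 passed (2.57, adjusted p = 0.00211), as did that between SEZ_GFPprom and DIEC_GFP without either SEZ_CD24 array (0.95, adjusted p = 0.0152) or in a fit of those groups alone (adjusted p = 0.0137). By its brightest probe set Cd24a was highest in the CD24 sort, at 11.47 ± 0.56, against 10.75 ± 0.19 in SEZ_GFP, 10.26 ± 0.31 in SEZ_GFPprom, 9.20 ± 0.52 in DIEC_GFP and 8.65 ± 0.85 in SEZ_Prom. Of its other 2 probe sets, 1 was also highest there (11.36), and the other averaged 8.70 in SEZ_CD24 against 9.60 in SEZ_GFP and 9.22 in SEZ_GFPprom. Cd24a was higher by the brightest probe set in SEZ_GFPprom than in DIEC_GFP (log2 1.06, adjusted p = 0.0423) and SEZ_Prom (adjusted p = 0.0314), and in SEZ_GFP than in DIEC_GFP (1.54, adjusted p = 0.0243). The SEZ_Prom and SEZ_CD24 arrays differed in Cd24a by -2.83 (log2, adjusted p = 0.00826), and SEZ_GFPprom and SEZ_CD24 by -1.21, which missed the threshold (adjusted p = 0.065) and passed it without either SEZ_Prom array (adjusted p = 0.0456) and without the dimmer 50% of genes (0.0433).

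**Figure D2:**
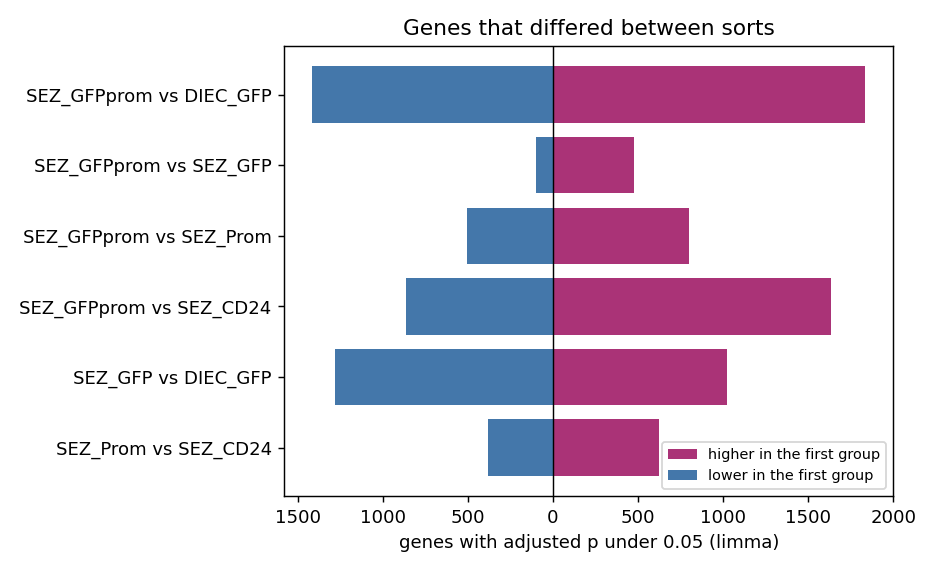
Bars give the number of genes with adjusted p under 0.05 (limma, x axis) that were higher (right) or lower (left) in the first of the groups named on the y axis. SEZ_GFPprom against DIEC_GFP gave 1832 higher and 1415 lower genes, and SEZ_GFPprom against SEZ_GFP 479 and 98.

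The comparison of SEZ_GFPprom with DIEC_GFP set cells labelled neural stem, of a neurogenic region, against cells labelled astrocytes, of the diencephalon. These groups differ in both region and the prominin gate, whose effects this comparison cannot separate. Thbs4, a secreted thrombospondin, was 63.9-fold higher in SEZ_GFPprom (adjusted p = 3.26e-06). The proliferation antigen Mki67 was 37.1-fold higher (10.49 ± 0.35 against 5.27 ± 1.32, SD, n = 4 each, adjusted p = 0.000123) and the interneuron-lineage homeobox gene Dlx1 33.7-fold higher. Aldh1a1, a retinaldehyde dehydrogenase, was 53.7-fold higher in DIEC_GFP (9.33 ± 1.28 against 3.58 ± 0.64, adjusted p = 0.000126), and the angiotensinogen gene Agt 15.9-fold higher. In all, 1832 genes were higher and 1415 lower in SEZ_GFPprom, of 18193 tested, and 1243 and 1082 of these differed at least 2-fold. The highest differences also included Cks2 (5.48), Scn4b (5.11), Rasd2 (4.83) and Spc25 (4.61) on the log2 scale. The lowest included Igsf1 (-4.75), Etnppl (-4.39), Gpr37 (-4.39), Klhl4 (-4.31), Klk6 (-4.22) and Chl1 (-4.15). With values under 10 set to 10, Cdca5 was higher by 5.31 and Adcy8 differed by -4.49.

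Of 40 cell cycle genes, 37 rose and 3 did not pass (37 rose when adjusted over the list alone), among them Mcm6 (15.3-fold), Ube2c (21.1-fold) and Hmgb2 (7.69-fold), with a list median of 3.15 and camera adjusted p = 3.36e-28. Of 23 neuroblast markers 11 rose and 12 did not pass (15 rose when adjusted over the list alone). Among them Dcx was 14.5-fold and Ccnd2 6.92-fold higher (camera adjusted p = 1.09e-06, and 0.166 with an estimated correlation). Neurogenic transcription factors rose in 11 of 18, and in 14 when adjusted over the list alone, with Sox11 17.5-fold and Meis2 18.0-fold higher (adjusted p = 5.06e-08). Telencephalic transcription factors rose in 5 of 9, and in 6 when adjusted over the list alone (adjusted p = 7.29e-05), as with Six3 (3.89-fold), Lhx2 (5.29-fold) and Gsx2 (5.04-fold). Of 25 stem cell and radial glia genes, 9 rose, 3 fell and 13 did not pass (11 and 3 when adjusted over the list alone; adjusted p = 0.03; adjusted p = 0.18 with an estimated correlation). Within that list Nr2e1, an orphan nuclear receptor of neural stem cells, was 5.11-fold higher, and Lrig1, a negative regulator of growth factor receptors, was 15.3-fold lower. This call was lost without SEZ_GFPprom replicate 1 (adjusted p = 0.073), without DIEC_GFP replicate 4 (0.106) and without the dimmer 50% of genes (0.194).

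Motile cilia are the beating organelles of ependymal cells. Of 18 ependymal markers 12 rose and 6 did not pass (14 rose when adjusted over the list alone), including Foxj1, the master regulator of motile cilia (4.16-fold), Rarres2 (5.47-fold) and Meig1 (5.34-fold), with adjusted p = 8.01e-08 (adjusted p = 0.166 with an estimated correlation). Rarres2 differed by 0.35 (adjusted p = 0.313) without probe sets of shared sequence. Motile cilium components rose in 22 of 60, and in 27 when adjusted over the list alone, with Armc4 4.19-fold and Ropn1l 6.07-fold higher (adjusted p = 6.59e-10; adjusted p = 0.11 with an estimated correlation). Intraflagellar transport and basal body genes rose in 8 of 40, the same number when adjusted over the list alone, with B9d1 2.97-fold higher (adjusted p = 0.0273; adjusted p = 0.18 with an estimated correlation). That call was lost without DIEC_GFP replicate 3, SEZ_GFPprom replicate 1 or SEZ_GFPprom replicate 4 (adjusted p = 0.0689 to 0.0735), and with the 3' to 5' signal ratio of the control transcripts as a covariate (0.109), where B9d1 missed the threshold too (adjusted p = 0.105).

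Astrocyte markers fell in 17 of 30 and rose in 0 (19 fell and 1 rose when adjusted over the list alone), with the gap junction gene Gjb6 12.8-fold, the GABA transporter Slc6a11 8.84-fold and the amino acid transporter Slc7a10 11.6-fold lower in SEZ_GFPprom (adjusted p = 1.21e-12; adjusted p = 0.18 with an estimated correlation). Oligodendrocyte markers fell in 9 of 12, and in 10 when adjusted over the list alone, with the myelin gene Mbp 2.31-fold and Ugt8a 7.27-fold lower (adjusted p = 1.36e-08; adjusted p = 0.166 with an estimated correlation). Oligodendrocyte progenitor markers fell in 9 of 10, and in 10 when adjusted over the list alone, with Olig1 9.33-fold, Cspg4 9.75-fold and Nkx2-2 11.4-fold lower (adjusted p = 6.52e-11). Microglia markers fell in 2 of 16, Ctss (2.62-fold) and Cx3cr1 (2.56-fold), and in 0 when adjusted over the list alone (adjusted p = 0.0273; adjusted p = 0.582 with an estimated correlation). That call was lost without SEZ_GFPprom replicate 2 or DIEC_GFP replicate 1 or 4 (adjusted p = 0.0818 to 0.139), without probe sets of shared sequence (0.0511) and with fry (0.386). Cx3cr1, Ctss and Cd24a, of 50 named genes past the threshold, missed it without 1 or another of the arrays (adjusted p = 0.0506 to 0.116) and with the 3' to 5' covariate (0.302, 0.138 and 0.134). DIEC_GFP replicates 1 and 4 and SEZ_GFPprom replicates 1 and 2 each ended all 3 calls, and the SEZ_GFP arrays, which lie outside the comparison, each ended those of Cd24a and Cx3cr1. A fit of the groups compared alone ended those of Ctss (0.0576) and Cx3cr1 (0.0809), and setting values under 10 to 10 those of Cx3cr1 (0.0714) and Cd24a (0.0589).

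Among metabolic genes, cholesterol synthesis genes fell in 13 of 20, and in 15 when adjusted over the list alone, with Msmo1 6.73-fold, Cyp51 4.35-fold and Dhcr7 4.43-fold lower (adjusted p = 6.52e-11). Glycolysis genes fell in 3 of 12 (5 when adjusted over the list alone; adjusted p = 9e-04; adjusted p = 0.234 with an estimated correlation). Interferon and antigen presentation genes fell in 4 of 18, and in 5 when adjusted over the list alone, with H2-Aa 8.37-fold lower (adjusted p = 0.000437; adjusted p = 0.106 with an estimated correlation). Fatty acid oxidation genes fell in 4 of 20 (5 when adjusted over the list alone; adjusted p = 0.0273; adjusted p = 0.363 with an estimated correlation). FGF and EGF pathway genes fell in 4 and rose in 1 of 18 (5 and 1 when adjusted over the list alone; adjusted p = 0.0404; adjusted p = 0.229 with an estimated correlation). The fatty acid call was lost without DIEC_GFP replicate 3, SEZ_GFPprom replicate 3 or DIEC_GFP replicate 1 (adjusted p = 0.0513 to 0.0775), and the FGF and EGF call without DIEC_GFP replicate 2 or SEZ_GFPprom replicates 1, 2 or 4 (0.0514 to 0.0817). With the 3' to 5' covariate 1486 genes differed in place of 3247 (768 higher and 718 lower), and the fatty acid (0.129) and FGF and EGF (0.109) calls were lost. The ratio itself averaged 5.40 ± 0.29 (log2, SD) in DIEC_GFP and 4.94 ± 0.18 in SEZ_GFPprom, so the covariate partly follows the groups. Other settings that ended the fatty acid call gave 0.0576 to 0.171 (filters on dim genes and fry), and those that ended the FGF and EGF call 0.0536 and 0.0545 (cyclic loess and no probe sets of shared sequence).

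**Figure D3:**
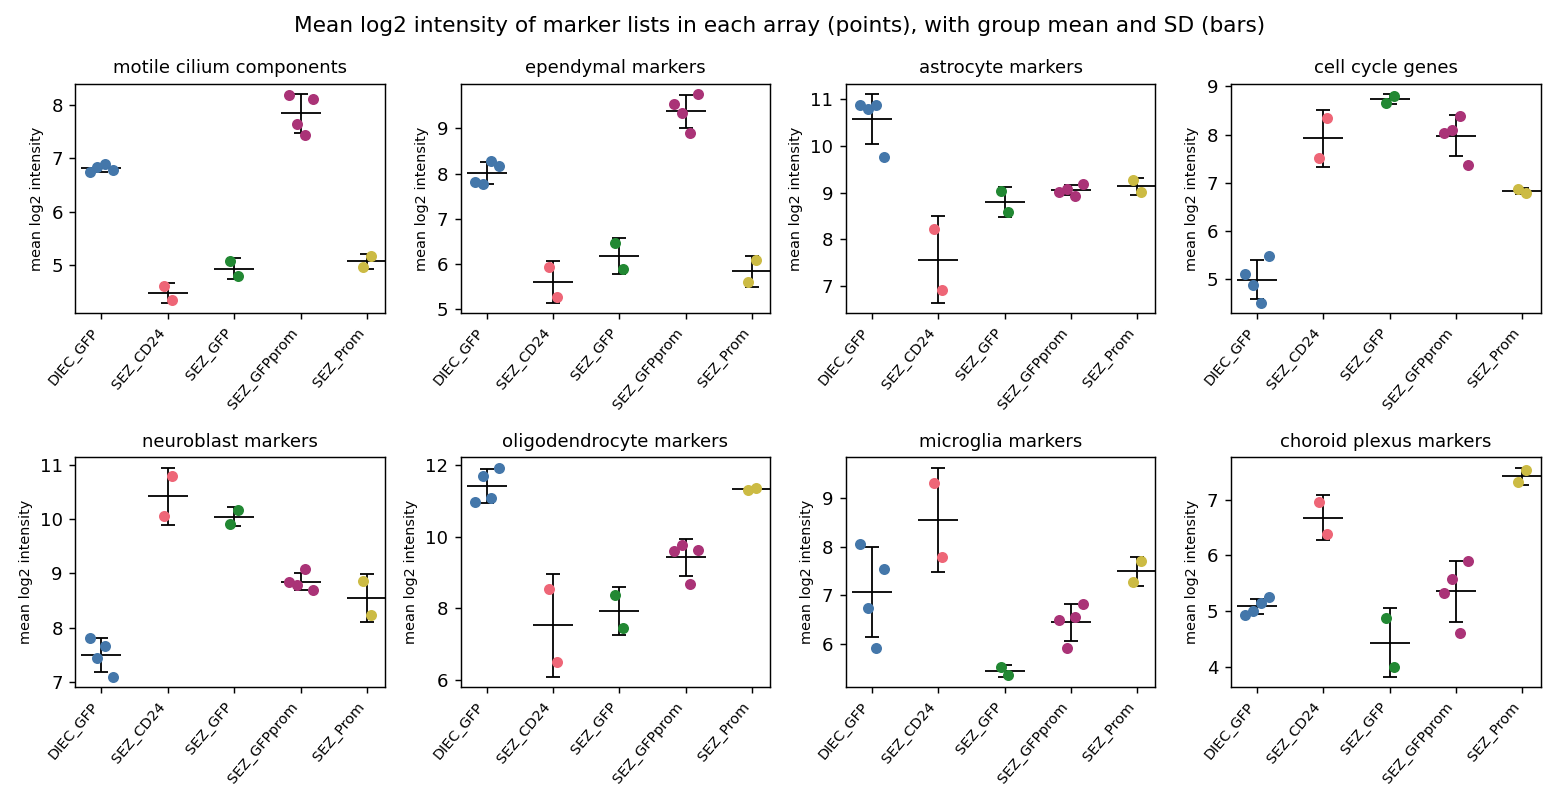
Each panel shows 1 marker list, each point the mean log2 intensity of its genes on 1 array (y axis), and the bars the mean and SD of each sort. Motile cilium components averaged 7.84 in SEZ_GFPprom, 6.82 in DIEC_GFP, 5.07 in SEZ_Prom, 4.94 in SEZ_GFP and 4.48 in SEZ_CD24.

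The comparison of SEZ_GFPprom with SEZ_GFP asked what prominin adds within the GFP-positive cells of the SEZ. Calb1, a calcium-binding protein, was 66.4-fold higher in SEZ_GFPprom (10.43 ± 0.34, SD, n = 4, against 4.38 ± 0.53, n = 2, adjusted p = 6.68e-05), Iqca 43.7-fold, and the cilium gene Cfap161 37.8-fold. Edaradd, an adaptor of the ectodysplasin receptor, was 11.5-fold lower (3.80 ± 0.15 against 7.33 ± 0.81, adjusted p = 0.000693), but its difference was 0.16 (adjusted p = 0.759) without probe sets of shared sequence, a setting chosen after seeing the data. The proteoglycan gene Cspg4 was 6.25-fold lower. In all, 479 genes were higher and 98 lower, of which 468 and 89 differed at least 2-fold. Fam183b (5.38), Ttc29 (5.36) and Slc26a3 (5.21) were also among the highest, and Tle2 (-2.42), Matn4 (-2.30), Nrxn3 (-2.30), Igsf9 (-2.25), Celsr3 (-2.19) and Tiam2 (-2.05) among the lowest. Capsl was higher by 5.78 and Efcab12 by 5.11 with values under 10 set to 10. The count was 320 without SEZ_GFP replicate 1 (275 higher and 45 lower), 198 without SEZ_GFP replicate 2 (184 and 14) and 1364 with array weights (967 and 397).

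Motile cilium components rose in 49 of 60 (56 when adjusted over the list alone), with Armc4 19.5-fold and Ak7 19.4-fold higher and Wdr63 higher by 3.90 on the log2 scale with values under 10 set to 10, a list median of 3.02 and adjusted p = 1.91e-60. Ependymal markers rose in 15 of 18, and in 16 when adjusted over the list alone, with Ccdc153 26.4-fold, Foxj1 13.3-fold and Tm4sf1 29.3-fold higher (adjusted p = 2.73e-27). Of 40 intraflagellar transport and basal body genes, 5 rose (14 when adjusted over the list alone), among them Wdr35 (3.28-fold) and B9d1 (3.49-fold), with adjusted p = 1.24e-06. Neuroblast markers fell in 3 of 23, Igfbpl1 (3.84-fold), Ncam1 (2.28-fold) and Nrxn3 (4.92-fold), and in 15 when adjusted over the list alone (adjusted p = 5.99e-15). Neurogenic transcription factors fell in 1 of 18, Pbx3 (3.43-fold), and in 3 when adjusted over the list alone (adjusted p = 5.43e-06; adjusted p = 0.0624 with an estimated correlation). Of 40 cell cycle genes 0 passed, over all genes or adjusted over the list alone, with a median of -0.79 (adjusted p = 7.74e-10; adjusted p = 0.29 with an estimated correlation). Mcm6 differed by -0.87 (adjusted p = 0.122) and Kif11 by -1.43 (adjusted p = 0.116).

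Of 12 oligodendrocyte markers 2 rose, Mbp (3.03-fold) and Mobp (10.9-fold), the same number when adjusted over the list alone (adjusted p = 1.74e-05; adjusted p = 0.363 with an estimated correlation). Oligodendrocyte progenitor markers fell in 1 of 10, again 1 when adjusted over the list alone (adjusted p = 0.000187; adjusted p = 0.18 with an estimated correlation). Microglia markers passed in 0 of 16, and 1 rose when adjusted over the list alone, with Ctss at 1.77 (adjusted p = 0.0652) and Csf1r at 1.62 (adjusted p = 0.163) on the log2 scale (list adjusted p = 0.00424; adjusted p = 0.567 with an estimated correlation). Mature neuron markers passed in 0 of 14, over all genes or adjusted over the list alone, with a median of 1.08 (adjusted p = 0.00382; adjusted p = 0.5 with an estimated correlation). Choroid plexus markers rose in 2 of 11, Sostdc1 (8.04-fold) and Clic6 (7.36-fold), and in 3 when adjusted over the list alone (adjusted p = 0.0184; adjusted p = 0.304 with an estimated correlation). Without SEZ_GFPprom replicate 4 or SEZ_GFP replicate 2 that call was lost (adjusted p = 0.0569 and 0.0731), as it was under 4 other settings, with 0.0536 in a fit of the groups compared alone up to 0.43 without the dimmer 50% of genes. Clic6 differed by 0.39 (adjusted p = 0.758) without probe sets of shared sequence. The mature neuron call was lost with the 3' to 5' covariate (0.0816) and without the dimmer 50% of genes (0.0527), and fry called neither it (0.169) nor the microglia list (0.22).

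Mural cell markers rose in 2 of 12, Acta2 (33.6-fold) and Tagln (4.46-fold), which encode smooth muscle proteins, and in 2 when adjusted over the list alone (adjusted p = 0.0486; adjusted p = 0.363 with an estimated correlation). Endothelial markers rose in 1 of 14, the glucose transporter Slc2a1 (4.20-fold), and in 1 when adjusted over the list alone (adjusted p = 0.0443; adjusted p = 0.526 with an estimated correlation). Without probe sets of shared sequence Acta2 differed by 0.11 (adjusted p = 0.878) and the mural call was lost (0.324). That call was also lost on leaving out any of 11 arrays in turn (adjusted p = 0.0519 to 0.0782), namely all but SEZ_GFP replicate 2 and SEZ_GFPprom replicates 1 and 3, and under other settings (0.0527 to 0.212), among them the 3' to 5' covariate (0.0607). The endothelial call was lost without DIEC_GFP replicate 3, SEZ_GFP replicate 1 or 2, or SEZ_GFPprom replicate 2 or 4 (adjusted p = 0.06 to 0.127), and under other settings, filters on dim genes among them (0.0547 to 0.173). Cholesterol synthesis genes passed in 0 of 20, over all genes or adjusted over the list alone, with a median of -0.39 (adjusted p = 0.000988; adjusted p = 0.29 with an estimated correlation; 0.128 with fry, which did not call the cell cycle list either, 0.107). Of 34 named genes past the threshold, B9d1, Celsr3, Clic6, Igsf9, Matn4, Mobp, Ncam1, Nrxn3, Pbx3, Slc2a1, Tiam2, Tle2 and Wdr35 missed it without SEZ_GFP replicate 1 or 2 (adjusted p = 0.0622 to 0.421). Igsf9, Ncam1 and Tle2 also missed it without 1 or another SEZ_GFPprom array (0.055 to 0.0968), and Ncam1 and Tle2 without a DIEC_GFP array (0.0518 to 0.0565). The mean of a gene's probe sets gave Ncam1 -0.59 (adjusted p = 0.0658), Nrxn3 -1.39 (0.0602) and Clic6 1.64 (0.0704). A fit of the groups compared alone ended the calls of Wdr35, Ncam1, Nrxn3, Pbx3 and Matn4 (0.0702 to 0.126), setting values under 10 to 10 those of Ncam1, Igsf9 and Tle2 (0.0539 to 0.0747), cyclic loess that of Ncam1 (0.0554) and the 3' to 5' covariate that of Tle2 (0.0535).

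The comparison of SEZ_GFPprom with SEZ_Prom asked what GFP adds within the prominin-positive cells. The dynein light chain gene Dynlrb2 was 93.0-fold higher in SEZ_GFPprom (11.24 ± 0.37, SD, n = 4, against 4.71 ± 0.87, n = 2, adjusted p = 8.95e-05). The intermediate filament gene Vim was 7.69-fold higher and the radial glial phosphatase gene Ptprz1 3.65-fold higher. Gpr37, a receptor of oligodendrocytes, was 20.1-fold lower (4.87 ± 0.28 against 9.20 ± 0.03, adjusted p = 0.00173), and the choroid plexus gene Kcnj13 was 17.6-fold lower. Kl, another choroid plexus gene, was 8.32-fold lower with values under 10 set to 10. In all, 800 genes were higher and 502 lower, and 741 and 445 of these differed at least 2-fold. Fam183b (5.94), Frmpd2 (5.69) and Iqca (5.59) were among the highest, and Klhl4 (-3.71), Rab40b (-3.70), Car12 (-3.70), Ldlrad4 (-3.42) and Rasgrp3 (-3.40) among the lowest. With values under 10 set to 10, Ttc29 was higher by 5.44, Cfap299 by 5.24, Rassf9 by 4.86 and Adgb by 4.36. The count of 1302 became 348 without SEZ_Prom replicate 1 (267 higher and 81 lower), 476 without SEZ_Prom replicate 2 (367 and 109) and 855 without SEZ_GFPprom replicate 1 (564 and 291).

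Of 60 motile cilium components 46 rose (56 when adjusted over the list alone), with Armc4 29.2-fold and Ak7 25.3-fold higher, a list median of 2.88 and adjusted p = 3.96e-44. Ependymal markers rose in 16 of 18, and in 16 when adjusted over the list alone, with Ccdc153 37.7-fold, Tmem212 31.3-fold and Foxj1 13.9-fold higher (adjusted p = 1.04e-24). Intraflagellar transport and basal body genes rose in 15 of 40, and in 23 when adjusted over the list alone, with Ift122 6.11-fold and Cep290 8.77-fold higher (adjusted p = 5.07e-10). Stem cell and radial glia genes rose in 9 of 25 and fell in 0 (11 and 0 when adjusted over the list alone), with Thbs4 4.70-fold and Notch2 3.43-fold higher besides Vim and Ptprz1 (adjusted p = 1.93e-07). Cell cycle genes rose in 8 of 40, and in 21 when adjusted over the list alone, with Mcm6 2.81-fold and Ube2c 3.56-fold higher (adjusted p = 1.67e-09; adjusted p = 0.237 with an estimated correlation).

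Choroid plexus markers fell in 6 of 11, and in 7 when adjusted over the list alone, among them Aqp1 (4.61-fold) and, with values under 10 set to 10, Slc4a5 (2.69-fold) and Kcne2 (3.44-fold), with a list adjusted p of 1.67e-09. Oligodendrocyte markers fell in 5 of 12, and in 9 when adjusted over the list alone, with Mbp 2.24-fold, Mobp 7.09-fold and Ermn 6.19-fold lower (adjusted p = 6.49e-08; adjusted p = 0.216 with an estimated correlation). Oligodendrocyte progenitor markers fell in 2 of 10, Olig1 (6.35-fold) and Nkx2-2 (4.41-fold), and in 3 when adjusted over the list alone (adjusted p = 8.42e-05; adjusted p = 0.15 with an estimated correlation). Microglia markers passed in 0 of 16, over all genes or adjusted over the list alone, with Ctss at -1.16 (adjusted p = 0.166) and P2ry12 at -2.22 (adjusted p = 0.175) on the log2 scale (list adjusted p = 0.00103; adjusted p = 0.523 with an estimated correlation).

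Several further calls of this comparison lay close to the threshold. Hedgehog pathway genes rose in 2 of 11 and fell in 1 (4 and 1 when adjusted over the list alone), with Gas1 3.25-fold higher and Hhip, which binds hedgehog ligands, 8.85-fold lower (adjusted p = 0.0486; adjusted p = 0.216 with an estimated correlation). Wnt pathway genes rose in 4 of 30, and in 5 when adjusted over the list alone, with the receptor Fzd8 4.08-fold higher (adjusted p = 0.0488; adjusted p = 0.191 with an estimated correlation). Neurogenic transcription factors passed in 0 of 18, over all genes or adjusted over the list alone, with a median of 0.42 (adjusted p = 0.0488; adjusted p = 0.444 with an estimated correlation). Glycolysis genes passed in 0 of 12, also when adjusted over the list alone, with a median of -0.37 (adjusted p = 0.0488; adjusted p = 0.589 with an estimated correlation). Mature neuron markers passed in 0 of 14, also when adjusted over the list alone, with Thy1 at -1.33 (adjusted p = 0.0953) and Camk2a at -1.81 (adjusted p = 0.103) on the log2 scale (list adjusted p = 0.0488; adjusted p = 0.718 with an estimated correlation). Each of these 5 calls was lost without SEZ_GFP replicate 1 or 2 (adjusted p = 0.0522), and each also without SEZ_GFPprom replicate 2 and further arrays of either group. On leaving out single arrays the highest adjusted p was 0.0717 for hedgehog, 0.0956 for Wnt, 0.435 for neurogenic, 0.148 for glycolysis and 0.177 for mature neuron genes. Leaving out DIEC_GFP replicate 1, 2 or 3, which lie outside the comparison, also ended some of the 5, and either SEZ_CD24 array ended the mature neuron call. With the 3' to 5' covariate the neurogenic (0.27), Wnt (0.197) and hedgehog (0.114) calls were lost. Further settings that ended calls gave 0.052 to 0.275 for neurogenic, 0.052 to 0.245 for glycolysis, 0.052 to 0.384 for mature neuron, 0.0544 and 0.0887 for hedgehog and 0.059 for Wnt genes. Fry did not call the microglia list (0.227).

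Of 41 named genes past the threshold in this comparison, 17 missed it without SEZ_Prom replicate 1 or 2 (adjusted p = 0.0569 to 0.309). These were Cd24a, Cep290, Ermn, Fzd8, Hhip, Kcnj13, Klhl4, Ldlrad4, Mcm6, Mobp, Nkx2-2, Notch2, Olig1, Rab40b, Rasgrp3, Thbs4 and Ube2c. Cd24a, Hhip, Ldlrad4, Nkx2-2, Rab40b and Rasgrp3 also missed it without 1 or another SEZ_GFPprom array (0.0506 to 0.0843), and Ldlrad4 without a SEZ_GFP array (0.052). Without probe sets of shared sequence Ift122 differed by 1.31 (adjusted p = 0.223), Mcm6 by 0.70 (0.429), Mbp by -0.80 (0.0577) and Ldlrad4 by -1.30 (0.101). Nkx2-2, Hhip, Rasgrp3, Ldlrad4 and Cd24a missed the threshold with the 3' to 5' covariate (0.0765 to 0.0955). By the mean of their probe sets Fzd8 differed by 1.22 (adjusted p = 0.198), Hhip by -1.94 (0.0839) and Mcm6 by 0.82 (0.0609). Nkx2-2, Rasgrp3, Ldlrad4 and Cd24a missed it in a fit of the groups compared alone (0.0582 to 0.0863), and Hhip, Rasgrp3, Ldlrad4, Rab40b and Cd24a with values under 10 set to 10 (0.0524 to 0.0652).

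The comparison of SEZ_GFPprom with SEZ_CD24 set a sort labelled neural stem against the sort labelled ependymal. Ccdc153, a gene of ciliated cells, was 93.1-fold higher in SEZ_GFPprom (12.56 ± 0.37, SD, n = 4, against 6.02 ± 0.75, n = 2, adjusted p = 9.07e-06). Alas2, the haem synthesis enzyme of red blood cell precursors, was 148.0-fold higher in SEZ_CD24 (12.42 ± 0.95 against 5.21 ± 0.55, adjusted p = 9.26e-06), and Tent5c 155.0-fold higher. In all, 1633 genes were higher and 863 lower in SEZ_GFPprom, and 1471 and 738 of these differed at least 2-fold. Fam183b (6.37), Dynlrb2 (6.35), Fam166c (6.07), Iqca (5.86), Ttc25 (5.79) and Ifitm3 (5.74) were also among the highest, and Aldh1a1 (-5.05), Rsad2 (-4.61), Slc25a37 (-4.43), Dusp6 (-4.16) and Fech (-4.15) among the lowest. With values under 10 set to 10, Ttc29 was higher by 5.44 and Gpr34 differed by -3.96. The count of 2496 became 1102 without SEZ_CD24 replicate 2 (716 higher and 386 lower) and 1580 in a fit of these groups alone (1077 and 503).

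Motile cilium components rose in 53 of 60, and in 57 when adjusted over the list alone, with Ak7 38.2-fold, Armc4 30.8-fold and Cfap54 19.2-fold higher, a list median of 3.61 and adjusted p = 1.79e-40. Ependymal markers rose in 16 of 18, again 16 when adjusted over the list alone, with Tmem212 47.7-fold and Tm4sf1 32.4-fold higher besides Ccdc153 (adjusted p = 1.2e-17). Intraflagellar transport and basal body genes rose in 19 of 40, and in 23 when adjusted over the list alone, with B9d1 11.3-fold and Ift74 6.96-fold higher (adjusted p = 3.2e-08). Stem cell and radial glia genes rose in 10 of 25, and in 12 when adjusted over the list alone, with Thbs4 12.5-fold and Ptprz1 3.09-fold higher and Id3 higher by 3.46 on the log2 scale (adjusted p = 1.35e-06). Astrocyte markers rose in 16 of 30, and in 20 when adjusted over the list alone, with Slc25a18 9.71-fold, Cbs 4.72-fold and the gap junction gene Gja1 4.01-fold higher (adjusted p = 3.12e-09; adjusted p = 0.277 with an estimated correlation). Fatty acid oxidation genes rose in 7 of 20 (8 when adjusted over the list alone; adjusted p = 0.000874; adjusted p = 0.232 with an estimated correlation). Among these Eci1 was 5.75-fold and Hadh 2.04-fold higher. Without probe sets of shared sequence the difference of Hadh was -0.12 (adjusted p = 0.892) and that of Fech -0.39 (adjusted p = 0.697).

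Neuroblast markers fell in 13 of 23, and in 19 when adjusted over the list alone, with Igfbpl1 4.66-fold, Nrxn3 5.67-fold, Ncam1 2.79-fold and Map1b 4.26-fold lower in SEZ_GFPprom (adjusted p = 1.26e-13). Neurogenic transcription factors fell in 8 of 18, and in 9 when adjusted over the list alone, with Dlx5 5.15-fold and Dlx2 4.42-fold lower (adjusted p = 0.000334; adjusted p = 0.113 with an estimated correlation). Microglia markers fell in 7 of 16, and in 11 when adjusted over the list alone, with Cx3cr1 13.9-fold, Ctss 5.15-fold and Tmem119 13.6-fold lower (adjusted p = 4.13e-08; adjusted p = 0.232 with an estimated correlation). Choroid plexus markers fell in 6 of 11, also 6 when adjusted over the list alone, with Kcnj13 10.8-fold and, with values under 10 set to 10, Kl 5.37-fold and Kcne2 3.75-fold lower (adjusted p = 6.24e-05; adjusted p = 0.0662 with an estimated correlation; 0.138 without the dimmer 25% of genes). Erythrocyte markers fell in 2 of 5, Alas2 and the anion exchanger Slc4a1 (6.60-fold), also 2 when adjusted over the list alone (adjusted p = 0.00804; adjusted p = 0.0662 with an estimated correlation).

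Oligodendrocyte markers rose in 6 of 12, and in 10 when adjusted over the list alone, with Ermn 7.65-fold and Opalin 12.2-fold higher in SEZ_GFPprom (adjusted p = 0.000874; adjusted p = 0.36 with an estimated correlation). Immediate early and stress genes fell in 3 and rose in 1 of 24 (4 and 1 when adjusted over the list alone), with Ier2 5.73-fold and Jun 3.69-fold lower (adjusted p = 0.000874; adjusted p = 0.374 with an estimated correlation). The oligodendrocyte call was lost without SEZ_CD24 replicate 2 (adjusted p = 0.113) and the immediate early call without SEZ_CD24 replicate 1 (0.119) or with fry (0.182). Of 49 named genes past the threshold, Ctss, Dlx2, Dlx5, Dusp6, Ermn, Hadh, Ier2, Jun, Kcnj13, Map1b, Ncam1, Opalin, Slc4a1 and Tmem119 missed it without SEZ_CD24 replicate 1 or 2 (adjusted p = 0.0527 to 0.207). Dusp6 also missed it without SEZ_GFPprom replicate 4 (0.0554), and Jun without SEZ_GFPprom replicate 2 or 3 (0.058 and 0.0579) and with the 3' to 5' covariate (0.0509). Averaged over its probe sets Opalin differed by 2.10 (adjusted p = 0.0918), Hadh by 0.46 (0.225) and Jun by -1.33 (0.0871). Dlx5, Slc4a1, Hadh and Jun missed it in a fit of the groups compared alone (0.0537 to 0.104), and Jun with array weights (0.0576) or values under 10 set to 10 (0.0525).

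The comparison of SEZ_GFP with DIEC_GFP set GFP-positive cells of a neurogenic region against those of a region taken as astrocytes. Cdca5, a cohesin regulator of dividing cells, was 79.2-fold higher in SEZ_GFP with values under 10 set to 10 (unaltered means 9.63 ± 0.21, SD, n = 2, against 3.03 ± 0.26, n = 4, adjusted p = 0.000141). Dlx1 was 91.6-fold and the neuroblast microtubule gene Dcx 49.9-fold higher. Aldh1a1 was 64.2-fold lower with values under 10 set to 10 (unaltered means 3.16 ± 0.23 against 9.33 ± 1.28, adjusted p = 0.000285). Agt was 48.7-fold and the myelin gene Mobp 47.8-fold lower. In all, 1020 genes were higher and 1282 lower, and 904 and 1192 of these differed at least 2-fold. Mki67 (5.97), Cks2 (5.93), Dlx1as (5.75), Mcm5 (5.55) and Pclaf (5.46) were also among the highest, and Gpr37 (-5.39), Igsf1 (-5.26), Lyz1 (-5.19) and Etnppl (-5.12) among the lowest. Cxcl2 differed by -4.73 with values under 10 set to 10. The count of 2302 became 1087 without SEZ_GFP replicate 1 (450 higher and 637 lower), 719 without SEZ_GFP replicate 2 (348 and 371), 1296 with the 3' to 5' ratio as a covariate (556 and 740) and 3558 with array weights (1602 and 1956).

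Cell cycle genes rose in 39 of 40, and in 39 when adjusted over the list alone, with Mcm6 27.8-fold and Ube2c 31.2-fold higher, a list median of 3.77 and adjusted p = 5.15e-40. Neuroblast markers rose in 18 of 23, and in 21 when adjusted over the list alone, with Igfbpl1 14.1-fold and Ccnd2 12.5-fold higher (adjusted p = 3.77e-19). Neurogenic transcription factors rose in 13 of 18, also 13 when adjusted over the list alone, with Sox11 35.4-fold and Meis2 28.4-fold higher (adjusted p = 3.74e-13). Telencephalic transcription factors rose in 5 of 9, also 5 when adjusted over the list alone, with Gsx2 9.51-fold and Lhx2 5.11-fold higher (adjusted p = 0.000476). Diencephalic transcription factors fell in 4 of 23, also 4 when adjusted over the list alone, with Irx2 4.84-fold, Irx3 15.8-fold and Otx2 6.71-fold lower (adjusted p = 0.0497; adjusted p = 0.214 with an estimated correlation). Leaving out any of 10 arrays in turn ended that call (adjusted p = 0.0523 to 0.064), namely all but DIEC_GFP replicates 2 and 4 and SEZ_GFPprom replicates 1 and 3, and so did the 3' to 5' covariate (0.102), setting values under 10 to 10 (0.0568) and leaving out probe sets of shared sequence (0.0542). Stem cell and radial glia genes rose in 5 and fell in 2 of 25 (9 and 4 when adjusted over the list alone), with Thbs4 33.4-fold higher (adjusted p = 0.0154; adjusted p = 0.124 with an estimated correlation). Without DIEC_GFP replicate 4 (adjusted p = 0.0534) or the dimmer 50% of genes (0.236) that call was lost.

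Astrocyte markers fell in 15 of 30, and in 20 when adjusted over the list alone, with Slc25a18 24.8-fold and Slc6a11 12.3-fold lower in SEZ_GFP besides Agt (adjusted p = 2.99e-11; adjusted p = 0.214 with an estimated correlation). Motile cilium components fell in 37 of 60, and in 47 when adjusted over the list alone. Among them Stoml3 was 10.6-fold, Ak7 7.87-fold and Iqcg 6.68-fold lower (adjusted p = 3.74e-24). Ependymal markers fell in 11 of 18, and in 13 when adjusted over the list alone. Among these Tm4sf1 was 21.3-fold and Ccdc153 7.88-fold lower (adjusted p = 1.52e-09, and 0.107 with an estimated correlation). Oligodendrocyte markers fell in 12 of 12, also when adjusted over the list alone, with Mbp at -2.81 and Mobp at -5.58 on the log2 scale (adjusted p = 1.6e-12; adjusted p = 0.106 with an estimated correlation). Oligodendrocyte progenitor markers fell in 5 of 10, and in 7 when adjusted over the list alone, with Olig1 7.25-fold lower (adjusted p = 3.79e-05; adjusted p = 0.106 with an estimated correlation). Microglia markers fell in 5 of 16, and in 7 when adjusted over the list alone, with Ctss 8.93-fold and Csf1r 4.71-fold lower (adjusted p = 6.19e-05; adjusted p = 0.298 with an estimated correlation).

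Cholesterol synthesis genes fell in 6 of 20, and in 8 when adjusted over the list alone, with Msmo1 4.54-fold lower (adjusted p = 8.95e-05; adjusted p = 0.124 with an estimated correlation). Glycolysis genes fell in 4 of 12, and in 7 when adjusted over the list alone, with Aldoa 2.41-fold lower (adjusted p = 0.000214; adjusted p = 0.214 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 20, and in 6 when adjusted over the list alone, with Hadh 2.40-fold lower (adjusted p = 0.0106; adjusted p = 0.29 with an estimated correlation), a call that was lost without SEZ_GFP replicate 2 (adjusted p = 0.184) and with the 3' to 5' covariate (0.12). Extracellular matrix genes fell in 6 and rose in 1 of 26 (6 and 2 when adjusted over the list alone), with Sparc 8.90-fold and Hapln2 7.63-fold lower (adjusted p = 0.0281; adjusted p = 0.106 with an estimated correlation; 0.102 with the 3' to 5' covariate and 0.0679 without the dimmer 50% of genes). Interferon and antigen presentation genes fell in 6 of 18, also 6 when adjusted over the list alone, with H2-Aa 9.99-fold lower (adjusted p = 0.00193; adjusted p = 0.107 with an estimated correlation). Of 46 named genes past the threshold, Aldoa, Cd24a, Csf1r, Cxcl2, Olig1 and Otx2 missed it without SEZ_GFP replicate 1 or 2 (adjusted p = 0.0508 to 0.173), Cd24a also without DIEC_GFP replicate 1 (0.0553). With the 3' to 5' covariate Otx2, Csf1r, Msmo1, Cxcl2 and Cd24a missed it (0.0605 to 0.138), and without probe sets of shared sequence Lyz1 differed by -0.24 (0.559). The mean of its probe sets gave Msmo1 a difference of -0.72 (adjusted p = 0.347). Csf1r (0.114) and Cd24a (0.0542) missed it in a fit of the groups compared alone.

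The comparison of SEZ_Prom with SEZ_CD24 set the prominin sort against the sort labelled ependymal, with 2 arrays each. Ermn, a cytoskeletal gene of myelinating oligodendrocytes, was 47.4-fold higher in SEZ_Prom (10.92 ± 0.08, SD, n = 2, against 5.36 ± 0.44, n = 2, adjusted p = 0.00239), Aspa 31.9-fold and Opalin 26.3-fold. Alas2 was 145.0-fold lower (5.24 ± 0.22 against 12.42 ± 0.95, adjusted p = 0.000507), and the interferon-induced gene Rsad2 65.0-fold. In all, 624 genes were higher and 382 lower, and 612 and 369 of these differed at least 2-fold. Gpr62 (5.20), Septin4 (4.70), Ppp1r14a (4.64) and Abca8a (4.64) were also among the highest, and Tent5c (-5.21), Isg20 (-4.88), Slc25a37 (-4.28), Elavl2 (-4.17), Dusp4 (-3.99) and Vcan (-3.91) among the lowest. Hhip was higher by 4.72 with values under 10 set to 10. The count of 1006 fell without SEZ_CD24 replicate 2, with a near even split of higher and lower genes. It was 213 without SEZ_Prom replicate 1 (115 and 98), 161 without SEZ_Prom replicate 2 (93 and 68) and 136 with the 3' to 5' ratio as a covariate (79 and 57). With limma on these 4 arrays alone 0 genes passed, 3492 had an unadjusted p under 0.05, and the lowest adjusted p was 0.15. Of 37 named genes past the threshold 23 missed it without 1 of the 4 arrays compared (adjusted p = 0.0502 to 0.229) and 22 with the 3' to 5' covariate (0.0525 to 0.245). The 23 were Aspa, Cd24a, Cx3cr1, Dcx, Dlx2, Dnal1, Dusp4, Elavl2, Gjb6, Hadh, Hhip, Isg20, Jun, Mag, Olig1, Olig2, Opalin, Ppp1r14a, S100b, Slc4a1, Sox11, Tent5c and Ube2c. Cx3cr1, Elavl2, Jun and Ppp1r14a also missed it without an array of another group. Averaged over their probe sets Dnal1 differed by 0.51 (adjusted p = 0.281), Cx3cr1 by -1.22 (0.115), Opalin by 3.27 (0.0532) and Ncam1 by 0.00051 (adjusted p = 1). Array weights ended the calls of Cx3cr1 (0.0502) and Elavl2 (0.0693), and setting values under 10 to 10 those of S100b, Jun, Cx3cr1, Ppp1r14a and Elavl2 (0.0502 to 0.0827). Those that passed without each of the arrays included Ermn, Alas2, Rsad2, Gpr62, Septin4, Abca8a and Vcan.

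Oligodendrocyte markers rose in 11 of 12, and in 12 when adjusted over the list alone, with Ugt8a 19.6-fold and Mag 15.1-fold higher (adjusted p = 7.27e-13; adjusted p = 0.132 with an estimated correlation). Oligodendrocyte progenitor markers rose in 3 of 10, and in 6 when adjusted over the list alone, with Olig1 7.57-fold and Olig2 5.28-fold higher (adjusted p = 0.000134; adjusted p = 0.162 with an estimated correlation). Astrocyte markers rose in 7 of 30, and in 23 when adjusted over the list alone, with S100b 6.29-fold and Gjb6 5.11-fold higher (adjusted p = 4.42e-12; adjusted p = 0.307 with an estimated correlation). Motile cilium components rose in 5 of 60, and in 6 when adjusted over the list alone, with Tppp3 13.8-fold and Dnal1 3.45-fold higher (adjusted p = 0.00117; adjusted p = 0.415 with an estimated correlation). With the 3' to 5' ratio as a covariate the cilium call was lost (adjusted p = 0.357), as it was with fry (0.0516). Choroid plexus markers rose in 1 of 11, Slc4a5 (2.46-fold with values under 10 set to 10), and in 1 when adjusted over the list alone (adjusted p = 0.0303; adjusted p = 0.353 with an estimated correlation; 0.453 with the 3' to 5' covariate and 0.351 and 0.768 without the dimmer 25% and 50% of genes). Fatty acid oxidation genes rose in 2 of 20, and in 7 when adjusted over the list alone, with Hadh 2.36-fold higher (adjusted p = 0.00039; adjusted p = 0.269 with an estimated correlation). Hadh differed by 1.23 (adjusted p = 0.173) without probe sets of shared sequence. Extracellular matrix genes rose in 4 and fell in 1 of 26 (7 and 1 when adjusted over the list alone), with Hapln2 13.2-fold higher and Vcan 15.0-fold lower (adjusted p = 0.0225; adjusted p = 0.132 with an estimated correlation). Mature neuron markers passed in 0 of 14, and 1 rose when adjusted over the list alone, with Thy1 at 1.90 on the log2 scale (adjusted p = 0.0501; list adjusted p = 0.0138; adjusted p = 0.625 with an estimated correlation).

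Neuroblast markers fell in 13 of 23, and in 17 when adjusted over the list alone. Among them Dcx was 11.8-fold and Igfbpl1 7.46-fold lower in SEZ_Prom (adjusted p = 3.77e-16, and 0.063 with an estimated correlation). Ncam1 was 6.01-fold lower by its brightest probe set, but of its 7 probe sets 2 passed in that direction and 2 in the opposite one. Neurogenic transcription factors fell in 8 of 18, and in 9 when adjusted over the list alone. Among them Dlx2 was 6.76-fold and Sox11 4.23-fold lower (adjusted p = 4.25e-08, and 0.063 with an estimated correlation). Cell cycle genes fell in 4 of 40, and in 12 when adjusted over the list alone, with Ube2c 3.44-fold lower (adjusted p = 5.76e-11; adjusted p = 0.259 with an estimated correlation). Erythrocyte markers fell in 2 of 5, Alas2 and Slc4a1 (11.4-fold), also 2 when adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.132 with an estimated correlation). Microglia markers fell in 1 of 16, Cx3cr1 (5.54-fold), also 1 when adjusted over the list alone (adjusted p = 0.00188; adjusted p = 0.612 with an estimated correlation). Immediate early and stress genes fell in 1 of 24, Jun (5.55-fold), and 3 fell and 1 rose when adjusted over the list alone (adjusted p = 5.19e-05; adjusted p = 0.415 with an estimated correlation). Without SEZ_CD24 replicate 1 the microglia call (adjusted p = 0.522) and the erythrocyte call (0.066) were lost, and fry called neither the microglia (0.29) nor the immediate early list (0.14). Without SEZ_CD24 replicate 2 the choroid plexus (0.0872), extracellular matrix (0.0527) and mature neuron (0.0527) calls were lost, and without SEZ_Prom replicate 2 the choroid plexus (0.101) and extracellular matrix (0.0557) calls. The erythrocyte call was also lost in a fit of the 4 arrays alone (0.0873), the extracellular matrix call without the dimmer 50% of genes (0.153) or probe sets of shared sequence (0.0784), and the mature neuron call without the dimmer 50% of genes (0.0576) or with fry (0.165).

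Genes that set SEZ_GFPprom apart from each of the other 4 groups were counted last. There were 211 genes higher in SEZ_GFPprom in all 4 comparisons and 5 lower. Of the 211, 34 belong to the ependymal or motile cilium lists and 23 carry clone or model names. Simulated arrays in which no group differed gave 0 genes in either direction at most, and independent lists would share 0.19 higher and 0.00998 lower genes. No gene differed in any comparison of that simulation, so it does not cover genes that already differ in some of them. With the SEZ_GFPprom arrays split between the comparisons, 89 to 148 genes were higher (median 102.5) and 2 lower. The largest smallest differences were those of Med9os (3.84), the smooth muscle actin gene Acta2 (3.76), the crystallin gene Crygn (3.44), the transglutaminase gene Tgm2 (3.05), Spaca9 (2.77), Calb1 (2.74), the desmosome gene Dsg2 (2.67), Tmem71 (2.63, or 2.28 with values under 10 set to 10), the interferon-induced gene Ifitm3 (2.61) and the cilium gene Ropn1l (2.54) on the log2 scale. Acta2 averaged 10.05 ± 0.64 (SD, n = 4) in SEZ_GFPprom and at most 6.29 ± 0.05 (n = 2, SEZ_Prom) elsewhere. Without probe sets of shared sequence the smallest difference of Acta2 was 0.11 and that of Tgm2 0.17. The 5 lower genes were Chfr, Tada1, Cyb5r1, Entr1 and Kif21b. By the mean of probe sets 6 genes were lower, 2 of them among these 5, and the smallest differences of Chfr (-0.89), Entr1 (-0.60) and Kif21b (-0.22) no longer went with a pass in all 4. With the 3' to 5' ratio as a covariate 63 higher genes were left, all of them among the 211. Tmem71 (2.27), Ifitm3 (1.36), Entr1 (-1.41) and Kif21b (-0.49) then no longer passed in all 4. Without SEZ_GFP replicate 2 there were 114, without SEZ_Prom replicate 1 there were 126, and without the dimmer 50% of genes 138. Of the genes named, Med9os, Tgm2, Calb1, Tmem71, Ifitm3, Chfr, Cyb5r1, Entr1 and Kif21b no longer passed in all 4 comparisons without 1 or another of the arrays, namely SEZ_CD24 replicate 1 or 2, SEZ_GFP replicate 1 or 2, SEZ_Prom replicate 1 or 2 or SEZ_GFPprom replicate 4. The count of 5 lower genes was 2 or 3 without an array of SEZ_GFP or SEZ_Prom, and 8 or 9 without DIEC_GFP replicate 4 or SEZ_GFPprom replicate 1, 3 or 4. It was 3 with the covariate or in fits of the groups compared alone, which ended the calls of Cyb5r1 and Entr1, and 12 with array weights. The trend and robust prior ended that of Kif21b.

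Across the 180 list tests 89 were called with the preset correlation and 24 with an estimated one. The 24 were cell cycle genes, neurogenic transcription factors and telencephalic transcription factors in SEZ_GFPprom and in SEZ_GFP against DIEC_GFP, and oligodendrocyte progenitor markers and cholesterol synthesis genes in SEZ_GFPprom against DIEC_GFP. They also held motile cilium components, ependymal markers and intraflagellar transport genes in SEZ_GFPprom against each of SEZ_GFP, SEZ_Prom and SEZ_CD24, with motile cilium components also in SEZ_GFP against DIEC_GFP. The rest were neuroblast markers in SEZ_GFPprom against SEZ_GFP and SEZ_CD24 and in SEZ_GFP against DIEC_GFP, stem cell and radial glia genes in SEZ_GFPprom against SEZ_Prom and SEZ_CD24, and choroid plexus markers in SEZ_GFPprom against SEZ_Prom. None lay in SEZ_Prom against SEZ_CD24. Of the 89 called lists none differed in sign between median, mean and test. Such differences were found only among lists that were not called, such as cell cycle genes in SEZ_GFPprom against SEZ_CD24 (adjusted p = 0.561), Wnt pathway genes in SEZ_Prom against SEZ_CD24 (0.998) and mature neuron markers in SEZ_GFPprom against DIEC_GFP (0.557). Notch pathway genes, BMP and TGF-beta pathway genes and sex-linked genes were not called by camera in any of the 6 comparisons, with lowest adjusted p of 0.113, 0.214 and 0.0698. The sex-linked list joins Xist with Y-linked genes, which go opposite ways where sex differs, so a test of 1 direction cannot decide on sex. In SEZ_GFPprom against SEZ_GFP its members differed by -1.855 to 4.267 (log2). Fry, which tests whether a list's genes move 1 way without setting them against other genes, called the Notch list in SEZ_GFPprom against SEZ_Prom (adjusted p = 0.045) and SEZ_CD24 (0.0215) and the sex-linked list in SEZ_GFPprom against DIEC_GFP (0.0146). It also called further lists that camera did not, such as mural cell markers (0.00135) and extracellular matrix genes (0.00141) in SEZ_GFPprom against SEZ_CD24.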

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

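Of the tests of explanations in this part, that of swapped arrays, that of more ependymal cells and that of a lower share of sorted cells were chosen after the result was seen, and so was the reading of the test of 9 erythroid genes.

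In 278 groups of 4 arrays, for named genes and list means, 26 had a highest or lowest array far from the other 3, and chance alone gives about 1 in 20. In DIEC_GFP, replicate 4 was low in Etnppl (log2 8.46), Slc7a10 (9.2), the mean of the astrocyte markers (9.77, the others 10.79 to 10.88) and that of the hedgehog genes (7.48), and high in Mki67 (7.24, the others 4.46 to 4.81). Replicate 1 was low in Dhcr7 (8.83) and high in Scn4b (6.38), and replicate 2 high in Gpr37 (10.95) and Msmo1 (11.24). In SEZ_GFPprom, replicate 3 was low in Ermn (7.09), Gja1 (11.71), Mbp (12.02), Tgm2 (8.7) and the mean of the oligodendrocyte markers (8.67, the others 9.59 to 9.77). Replicate 1 was high in Aqp1 (3.58), Eci1 (10.04) and Slc4a5 (2.81) and low in Meis2 (10.43). Replicate 2 was low in Gpr34 (2.32), Kl (2.58) and Pbx3 (8.16) and high in Igsf1 (5.93) and Klhl4 (4.95). Replicate 4 was low in Cdca5 (6.6) and Mcm6 (8.26) and high in Slc4a1 (5.55). For Aqp1, Slc4a5, Gpr34 and Kl the other 3 arrays held 1 identical rounded intensity, so their gap is a step of rounding.

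Among 10092 probe sets without a single gene name, which the gene tests left out, 14 were higher in SEZ_GFPprom than in each of the other 4 groups and 2 lower.

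Motile cilium genes were higher in SEZ_GFPprom than in the sort labelled ependymal and in the other SEZ sorts. Of the 5 groups, SEZ_CD24 had the lowest mean of ependymal markers (5.59, against 8.01 in DIEC_GFP) and of cilium components (4.48). It had the highest means of neuroblast (10.42) and microglia markers (8.55). Its label was thus not borne out by the ependymal list, and the comparison cannot be read as one with ependymal cells. A swap of the SEZ_CD24 and SEZ_GFPprom arrays would place the lower Gfap in SEZ_GFPprom, but Gfap was higher there by 3.52 (adjusted p = 0.00235), which argues against it. That value is of the brightest of 3 probe sets, of which 2 passed in this direction. Without probe sets of shared sequence a dimmer one was left (5.37 against 4.54), with a difference of 0.83 (adjusted p = 0.128). With the 3' to 5' ratio as a covariate, which moved genes by a median of 0.101, the smallest list median over the 3 comparisons was 3.15 (2.88 without it) and the highest camera adjusted p was 1.73e-40, which argues against RNA quality as the whole cause. The ependymal list, which shares 0 genes with the cilium list, had a smallest median of 3.73. It holds genes of motile cilia such as their regulator Foxj1, so it would rise with cilium genes in any ciliated cell. More ciliated ependymal cells in the SEZ_GFPprom sort therefore cannot be told apart from cilium genes in the sorted cells themselves.

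Of 12 oligodendrocyte markers 9 were higher in DIEC_GFP and 5 in SEZ_Prom than in SEZ_GFPprom, and with an estimated correlation neither list call held (adjusted p = 0.166 and 0.216). A lower share of the sorted cells in SEZ_Prom was tested as an equal rise of other cell types. Against SEZ_GFPprom oligodendrocyte markers had a median of 2.08 (95% interval 1.35 to 2.33), choroid plexus markers 2.12 (1.14 to 3.00) and microglia markers 1.18 (0.65 to 1.46). Mature neuron markers had 0.79 (0.01 to 1.81) and neuroblast markers, the only 1 of the 5 lists with a median under 0, -0.34 (-0.58 to 0.15). The gap between the intervals of the highest and lowest list was 0.991, which argues against an equal rise of all 5. It cannot decide on a lower share, since the rise of a list also depends on its signal in the sorted cells. The intervals draw a list's genes and hold no spread between arrays. RNA in myelin debris without oligodendrocytes could not be told apart from oligodendrocytes by 4 nuclear factors measured, with a smaller median of 1.15. Of these only Nkx6-2 and Zfp536 passed against DIEC_GFP and only Nkx6-2 against SEZ_Prom. The progenitor list, which holds the nuclear factors Olig1, Olig2, Sox10 and Nkx2-2, was higher in DIEC_GFP in 9 of 10 genes. In SEZ_Prom 2 of its genes were higher, Olig1 and Nkx2-2, and 8 did not pass. These genes mark progenitors, so they do not decide between debris and oligodendrocytes.

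Of 5 erythrocyte markers 2, Alas2 and Slc4a1, were higher in SEZ_CD24 than in SEZ_GFPprom and 3 did not pass, and the list call was lost with an estimated correlation (adjusted p = 0.0662). Of 9 further erythroid genes 2 were higher, Bpgm (2.51) and Trim10 (2.97), and the others did not pass, which under the bound set beforehand would argue against erythroid cells in the sort. However, 6 of the 9 lay under the median of all genes (5.88) in both groups. The absence of erythroid cells would give such dim values, and so would probe sets that read poorly. Sptb lay above that median and did not rise either (7.55 in SEZ_CD24 against 8.33 in SEZ_GFPprom, limma adjusted p = 0.356). The reading that the test decides nothing was chosen after these values were seen and can void only a negative outcome. The brightest probe set naming several globin genes was higher by 2.92 (14.2 against 11.28), as erythroid cells would give. It ranged from 9.86 to 12.82 among the SEZ_GFPprom arrays and from 9.09 to 12.54 among the DIEC_GFP arrays, so globin signal varied and was not confined to SEZ_CD24. By the bounds set beforehand the 9 genes and the globin probe sets thus go opposite ways. Erythroid cells in the SEZ_CD24 sort may be the source, and other sources of these transcripts stay open.

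Of the 35 splits of the 8 SEZ_GFPprom and DIEC_GFP arrays, the real one gave 3247 changed genes and the highest other 2. Only the real split gave as many, which argues against chance. With 35 splits 1 is the smallest number the test can give, so chance is not excluded. The splits also take the arrays as independent, which the labels do not state.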

How the results depend on the processing

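The alternatives of values under 10 set to 10 and of probe sets of shared sequence left out were chosen after the data were seen. Over all alternatives and arrays left out, named genes kept their direction and side of the threshold in 7052 tests, missed it in 366, newly passed in 45 and changed direction in 8. List tests kept their call in 2338 and lost it in 240, genes apart in 359 and 40, and counts stayed within 1.5 times in 209 and moved in 36. Fits that leave a group with 1 array assume that it varies like the other groups. Rescaling moved the median of all genes by at most 0.0189.

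Unless a cause is given, the cause was not tested. Leaving out the dimmest 50% of genes gave 138 genes apart and higher, with fewer genes tested. Fits of only the groups compared gave 1580 genes for SEZ_GFPprom against SEZ_CD24, 3 apart and lower, and 0 for SEZ_Prom against SEZ_CD24 (limma, 3492 at unadjusted p under 0.05, lowest adjusted p 0.15), with fewer arrays to estimate the spread. Array weights gave 1364 for SEZ_GFPprom against SEZ_GFP, 3558 for SEZ_GFP against DIEC_GFP and 12 apart and lower. The 3' to 5' covariate gave 1486 for SEZ_GFPprom against DIEC_GFP, 1296 for SEZ_GFP against DIEC_GFP, 136 for SEZ_Prom against SEZ_CD24, 63 apart and higher and 3 lower. That ratio differed between the sorts, with means of 5.398 in DIEC_GFP, 5.147 in SEZ_CD24, 4.941 in SEZ_GFPprom, 4.725 in SEZ_GFP and 4.626 in SEZ_Prom (log2). With an estimated correlation 24 list tests passed.

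The labels do not pair the arrays. The deviations of arrays with equal numbers correlated at a median r of 0.0052 over 22 pairs (-0.188 to 0.129, across genes), and those with different numbers at -0.0006 over 54. A block per replicate number gave 811 genes for SEZ_GFPprom against SEZ_Prom and 3 apart and lower, with Entr1 and Kif21b no longer among them. With it 17 calls of named genes and 6 of lists were lost.

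Leaving out single arrays gave 2172 to 3323 genes for SEZ_GFPprom against DIEC_GFP. It gave 198 to 646 against SEZ_GFP (198 without SEZ_GFP replicate 2, 320 without replicate 1) and 348 to 1525 against SEZ_Prom (348 and 476 without SEZ_Prom replicates 1 and 2, 855 without SEZ_GFPprom replicate 1). It gave 1102 to 2649 against SEZ_CD24 (1102 without SEZ_CD24 replicate 2), and 719 to 2690 for SEZ_GFP against DIEC_GFP (719 and 1087 without SEZ_GFP replicates 2 and 1). For SEZ_Prom against SEZ_CD24 it gave 161 to 1197 (161 and 213 without SEZ_Prom replicates 2 and 1, 202 without SEZ_CD24 replicate 2). Genes apart and higher ranged from 114 to 248 (114 without SEZ_GFP replicate 2, 126 without SEZ_Prom replicate 1). Those lower ranged from 2 to 9 (2 and 3 without SEZ_GFP replicates 2 and 1, 3 without either SEZ_Prom array, 8 without DIEC_GFP replicate 4 or SEZ_GFPprom replicate 4, 9 without SEZ_GFPprom replicate 1 or 3). Called lists ranged from 80 to 91.

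Gfap in SEZ_GFPprom against DIEC_GFP ranged from -0.26 to 0.60 and changed direction without DIEC_GFP replicate 4 (-0.07) or SEZ_GFPprom replicates 1 (-0.26) and 2 (-0.08). Prom1 ranged from -0.55 to 1.61 in SEZ_Prom against SEZ_CD24 and from -0.10 to 0.41 in SEZ_GFP against DIEC_GFP, with the lowest values, of the opposite direction, without SEZ_CD24 replicate 1 and SEZ_GFP replicate 2. The mean of its probe sets gave Ncam1 a difference of 0.00051 in SEZ_Prom against SEZ_CD24. Without probe sets of shared sequence Hadh differed by -0.12 in SEZ_GFPprom against SEZ_CD24 and Edaradd by 0.16 in SEZ_GFPprom against SEZ_GFP, since another probe set then stands for the gene.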

Other observations

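The hybridisation controls of SEZ_GFPprom replicate 3 averaged log2 8.58, against 9.72 to 10.4 in the other 13 arrays. Xist, which is transcribed in female cells, ranged from 6.19 to 11.38 among the DIEC_GFP arrays and from 6.98 to 11.39 among the SEZ_GFPprom arrays. It stood at 5.25 and 6.38 in SEZ_GFP, 11.69 and 11.78 in SEZ_CD24 and 9.79 and 10.46 in SEZ_Prom. The Y-linked gene Eif2s3y ranged from 6.74 to 8.30 among the DIEC_GFP arrays and from 5.32 to 6.87 among the SEZ_GFPprom arrays. It stood at 7.69 and 8.34 in SEZ_GFP, 6.38 and 6 in SEZ_CD24 and 6.54 and 5.55 in SEZ_Prom. No fit held sex as a term.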
